A study of Homo sapiens with 36 samples.

How the data were processed

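RNA sequencing of 36 libraries was taken from the deposited processed tables, 12 in number. Of these, 6 compare sulforaphane (15 µM) with DMSO (0.03%) in PrEC, LNCaP or PC3 at 6 h or 24 h, and 6 compare the DMSO groups of 2 cell types at the same time. Each table names its 2 groups, and each group has 3 library columns that carry no replicate number. Reads were processed with CASAVA 1.8.1, aligned to hg19/GRCh37 with TopHat 1.3.3 and Bowtie 0.12.9 and tested with Cuffdiff 1.3.0, per the submitters' processing notes. The tool that counted reads per gene and the test behind the deposited count p-values are not given in the sources used here.

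The deposited count of each library is a raw number of reads per gene. The deposited signal of each group is the authors' average of scaled counts over its 3 libraries. The deposited log2 fold is the authors' log2 ratio of the second group's average to the first group's. The deposited p-value and q-value are those of the authors' count test. The FPKM of each group, with its own log2 ratio, p-value and q-value, is the authors' Cuffdiff output, per the file headers. Genes with an entry from Cuffdiff alone (860 in the sulforaphane tables) have no counts and were left out, and 72 other per-sample columns were not used.

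The tables hold only genes that passed the authors' thresholds, so unlisted genes have no values. Column sums over listed genes are not the depth of a library. Of 126657 library and gene values present in more than a single table, 0 differed between tables. Replicate pairs within groups (36) had a chi-square per degree of freedom of 2.03 to 23.83, so that no pair was a copy. Tables were scaled separately, and tests were made only within a table or as contrasts of the groups of 2 tables.

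The files were first assumed to hold no library counts, and the authors' Cuffdiff test had been set as the main test. Because counts were present, edgeR was used instead. Library scaling factors were recovered by weighted regression of 3 times the authors' group average on the 3 count columns. Each table was then fitted with edgeR's quasi-likelihood functions with robust estimation, on the 2 groups of the table. P-values were adjusted by Benjamini-Hochberg over the 12721 genes listed with counts in any table, and a gene was called at an adjusted p under 0.05. Scaled means are given with SD and log2 fold changes with SE. A gene with 0 counts in a group was given a bound from a floor of 3 counts over the group. Differences of the sulforaphane effect between times or cell types were edgeR contrasts over the libraries of 4 groups, adjusted over the genes listed in both tables. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the data.table package, version 1.17.8.

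Lists of genes, named before the data were examined, covered NRF2 targets, heat shock chaperones, unfolded protein and ATF4 genes, mitosis, DNA replication, p53 targets, apoptosis regulators, androgen receptor targets, cholesterol synthesis, NF-kB and cytokine genes, interferon-stimulated genes, hypoxia and glycolysis, immediate early genes, metallothioneins, histone deacetylases and DNA methyltransferases, SP and KLF factors, housekeeping controls, ribosomal proteins and markers of basal, luminal, adhesion, mesenchymal, fibroblast, neuroendocrine, endothelial and leukocyte identity. A list of at least 5 members was tested in each direction with a Fisher's exact test, adjusted by Benjamini-Hochberg over lists, directions and tables (264 tests for sulforaphane and 264 for cell types). The background for sulforaphane was every gene listed in a table of the same time that compares the cell type with another. Members outside the background were counted but did not enter the test. Members were also counted after adjustment over the list alone. Overlaps of calls were tested with Fisher's exact test and, for tables that share a DMSO group, set against simulations without effect.

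Named genes are the 10 largest folds in each direction by the authors' log2 fold (FPKM of at least 5 in the higher and 0.5 in the lower group, or 10 and 0.1 for cell types), up to 4 called members of largest fold per list, and a fixed set that includes HMOX1, NQO1, GCLM, TXNRD1, SRXN1, CDKN1A, KLK3, SP1 and HDAC3. For differences they are the 10 largest. The text gives a selection of these, chosen for biology after the values were seen. Entries with several symbols or none were counted and not named. Coordinates are those of hg19, and the tables carry no strand.

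The alternatives were an adjusted p under 0.01, an absolute log2 fold change of at least 1, an FPKM of at least 1, adjustment over the listed genes only, the authors' tests, DESeq2, TMM over the listed genes or over all genes with counts in both groups, centring on the median of expressed listed genes, removal of each library's GC trend, a replicate block for the 2 sets of library numbers, the ratio of FPKM with a pseudocount of 1 or 0.1 for named genes and leaving out each library in turn. The scripts were tested on simulated data with 200 changed genes. In the sulforaphane comparisons, 38.8% to 83.6% of genes changed 1.5-fold, 88.1% to 100% of those changed 2-fold and 97% to 100% of those changed 4-fold were recovered. For cell type comparisons these were 37.3% to 83.6%, 82.1% to 98.5% and 95.5% to 100%, and for differences 37.3% to 83.6%, 80.6% to 97% and 98.5% to 100%.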

Results

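Total RNA of cultured human prostate cells was made into cDNA libraries and sequenced to ask which genes sulforaphane, an isothiocyanate formed when cruciferous vegetables are cut or chewed, changes in normal and in cancerous epithelium. PrEC are normal prostate epithelial cells, LNCaP is a prostate cancer line that depends on androgen, and PC3 is one that does not. Cells received 15 µM sulforaphane, or DMSO at 0.03% of the medium as the vehicle control, for 6 h or 24 h. This gave 12 groups of 3 libraries, 36 libraries in all. The labels do not say whether the 3 libraries of a group came from separate cultures, so every p-value measures the spread between these libraries only. The deposited tables list only genes that passed the authors' tests, and the folds below are therefore folds of genes selected for a difference.

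Counts could be summed only over listed genes, and the sums are a lower limit of the depth. In the DMSO groups, whose libraries appear in 3 tables each, a PrEC library held 7408899 to 9176706 counts over 10735 genes at 6 h and 8170467 to 10227383 over 11789 genes at 24 h. An LNCaP library held 8477174 to 9088749 counts over 11248 genes at 6 h and 9241017 to 10971447 over 11714 genes at 24 h. A PC3 library held 7760036 to 8912867 counts over 11267 genes at 6 h and 9554684 to 11461556 over 11753 genes at 24 h. Libraries with sulforaphane appear in 1 table each. Their sums ran from 2416689 to 2922678 over 3251 genes (PrEC, 6 h), 3163080 to 3751038 over 3305 genes (PrEC, 24 h) and 2003350 to 2252087 over 2793 genes (LNCaP, 6 h). They ran from 1979334 to 2176877 over 2590 genes (LNCaP, 24 h), 2682673 to 3088362 over 3004 genes (PC3, 6 h) and 3987341 to 4741410 over 3658 genes (PC3, 24 h).

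The first comparison asked what normal prostate epithelial cells did in the first 6 h with sulforaphane. In PrEC, HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1 (chromosome 22, 35777060 to 35790207 in hg19, ENSG00000100292), rose 54.3-fold, from a scaled count of 46.2 ± 16.2 to 2507 ± 128 (SD, n = 3; log2 fold change 5.76 ± 0.20 SE, adjusted p = 2.7e-06). NRF2 targets, which include the enzymes that make and recycle glutathione, rose in 15 of 28 measured members (15 adjusted over the list alone; Fisher's exact test, adjusted p = 9.82e-10), and the other 13 did not pass or were not listed. The test of each list used only members in its background, here 14 called of 23, so its p-value rests on fewer members than the counts beside it. Among those that rose were SLC7A11, the cystine transporter, at 25.8-fold (log2 4.69 ± 0.16), SRXN1 at 7.79-fold (2.96 ± 0.10), GCLM at 6.18-fold (2.63 ± 0.10) and NQO1 at 1.92-fold (0.94 ± 0.09). Heat shock chaperones rose in 11 of 18 members (12 adjusted over the list alone; adjusted p = 5.12e-07), with DNAJB4 11.0-fold and HSPH1 7.21-fold higher. HSPA1B was 26.0-fold higher (4.70 ± 0.12), although its reads can be shared with the near-identical HSPA1A. Genes of the unfolded protein and ATF4 response, which cells switch on when amino acids or protein folding fail, rose in 13 of 18 members (14 adjusted over the list alone; adjusted p = 2.73e-10). CHAC1, a glutathione-degrading enzyme, went from 26.4 ± 2.29 to 392 ± 50.3 (14.8-fold), and TRIB3 was 2.90-fold higher (1.54 ± 0.09).

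On the lower side in PrEC at 6 h were genes of inflammatory signalling. The neutrophil chemokine CXCL1 (chromosome 4, 74735109 to 74736955, ENSG00000163739) dropped from 779 ± 39.1 to 34.1 ± 2.98, which is 22.9-fold lower (log2 -4.51 ± 0.12 SE, n = 3, adjusted p = 2.5e-07). CXCL2 was 25.0-fold lower and the NF-kB inhibitor TNFAIP3 5.65-fold lower, and 9 of 16 NF-kB and cytokine genes fell (9 adjusted over the list alone; adjusted p = 0.00264). The homeobox gene HOXB13, a marker of the luminal lineage, was 4.11-fold lower. DNA replication genes fell in 12 of 20 members (12 adjusted over the list alone; adjusted p = 0.00135), with CDT1 1.83-fold lower (-0.87 ± 0.10), but 0 of them passed edgeR's test once the log2 fold changes were centred on the median of the listed genes (1 at an unadjusted p under 0.05). Of 21 mitosis genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone), which became 7 and 0 after centring (0 fell at an unadjusted p under 0.05) and 2 and 0 once each library's GC trend was removed, with MKI67 1.56-fold higher. Of 15 p53 targets, 2 rose and 5 fell (2 and 6 adjusted over the list alone), and the 5 fell to 0 after centring (0 at an unadjusted p under 0.05). Hypoxia and glycolysis genes rose in 1 and fell in 3 of 14 members (the same counts adjusted over the list alone), with the hexokinase HK2 2.11-fold lower. By edgeR's quasi-likelihood test, 2909 of 3251 listed genes passed an adjusted p of 0.05, 887 higher and 2022 lower (69.5% lower). This split turned with the scaling. Centring, a shift of 0.54 on the log2 scale, gave 1020 higher and 574 lower, and TMM over the listed genes gave 1003 and 773. Removing each library's GC trend gave 556 and 1372. That removal took the mean GC of the listed genes as its reference and so kept their mean log2 fold change. It therefore cannot judge the split.

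In PrEC after 24 h, the comparison asked what lasted or came later. The aldo-keto reductase gene AKR1C1 (chromosome 10, 5005454 to 5020158, ENSG00000187134), whose reads can be shared with AKR1C2 and AKR1C3, went from 95.6 ± 6.36 to 9488 ± 302 (SD, n = 3), a 99.2-fold rise (log2 6.63 ± 0.09 SE, adjusted p = 3.7e-09). NRF2 targets rose in 23 of 28 members (23 adjusted over the list alone; adjusted p = 7.79e-20). AKR1B10 was 29.2-fold higher (4.87 ± 0.12), the iron store FTL 9.38-fold (3.23 ± 0.15), HMOX1 7.37-fold (2.88 ± 0.21) and NQO1 5.08-fold (2.34 ± 0.08). Heat shock chaperones still rose in 10 of 18 members (10 adjusted over the list alone; adjusted p = 0.000127), with HSPB8 3.69-fold and DNAJB4 3.21-fold higher. Hypoxia and glycolysis genes rose in 7 of 14 members (7 adjusted over the list alone; adjusted p = 0.000127), among them the prolyl hydroxylase EGLN3 at 7.87-fold (2.98 ± 0.18), the vasodilator peptide ADM at 3.77-fold (1.92 ± 0.15) and the mitophagy receptor BNIP3 at 2.86-fold. Of 15 p53 targets, 5 rose (7 adjusted over the list alone; adjusted p = 0.0352). CDKN1A, the cell cycle inhibitor p21, was 3.56-fold higher (1.83 ± 0.14) and BAX 1.71-fold higher.

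All 21 mitosis genes were lower in PrEC at 24 h (21 adjusted over the list alone; adjusted p = 4.13e-12). The kinase PLK1 (chromosome 16, 23690201 to 23724821, ENSG00000166851) was 4.10-fold lower (log2 -2.04 ± 0.11 SE, n = 3, adjusted p = 8.6e-06), and the proliferation marker MKI67 was 4.75-fold lower, from 3455 ± 568 to 727 ± 51.2. DNA replication genes fell in 15 of 20 members (15 adjusted over the list alone; adjusted p = 8.87e-08), with CDT1 3.00-fold and CDC45 2.27-fold lower, though only 3 were lower after centring. Unfolded protein and ATF4 genes fell in 10 of 18 members (10 adjusted over the list alone; adjusted p = 0.00127). TRIB3 dropped from 5951 ± 711 to 945 ± 137, 6.29-fold lower (-2.65 ± 0.13), and asparagine synthetase ASNS was 4.22-fold lower (-2.08 ± 0.15). NF-kB and cytokine genes fell in 9 of 16 members (10 adjusted over the list alone; adjusted p = 0.00221), of which 5 were lower after centring, with CXCL2 7.61-fold lower and the prostaglandin synthase PTGS2 also lower (-2.27 ± 0.17). The alarmin IL33 was 9.89-fold lower (-3.31 ± 0.31). KLK3, the gene of prostate-specific antigen, did not pass (log2 2.67 ± 1.18, adjusted p = 0.22), though it did with DESeq2 (2.73), and without 1 of the sulforaphane libraries the log2 fold change was 0.74. The test called 2914 of 3305 listed genes, 990 higher and 1924 lower (66% lower). Centring, a shift of 0.56, gave 1075 higher and 467 lower, and TMM over the listed genes 1070 and 726.

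For LNCaP at 6 h the question was how an androgen-dependent cancer line responded at first. HMOX1 rose 27.3-fold, from 221 ± 6.2 to 6033 ± 762 (SD, n = 3; log2 4.77 ± 0.10 SE, adjusted p = 9.5e-12). OSGIN1, an oxidative stress gene, rose 12.5-fold (3.65 ± 0.10), the glutamate-cysteine ligase subunit GCLM 5.50-fold (2.46 ± 0.08) and NQO1 2.37-fold (1.24 ± 0.06). NRF2 targets rose in 16 of 28 members (16 adjusted over the list alone; adjusted p = 1.77e-10) and heat shock chaperones in 14 of 18 (14 adjusted over the list alone; adjusted p = 5.95e-10), with BAG3 5.53-fold (2.47 ± 0.12) and DNAJB4 6.06-fold higher. Of 15 p53 targets, 7 rose (7 adjusted over the list alone; adjusted p = 0.000243), including MDM2 at 2.07-fold (1.05 ± 0.09) and CDKN1A at 2.03-fold (1.02 ± 0.11). Unfolded protein and ATF4 genes rose in 6 and fell in 3 of 18 members (6 and 3 adjusted over the list alone; adjusted p = 0.00683 for the higher side). ATF3 was 2.48-fold higher while CHAC1 was 3.31-fold lower (-1.73 ± 0.13). Mitosis genes rose in 7 of 21 members (7 adjusted over the list alone; adjusted p = 0.00135), with AURKA 1.45-fold higher.

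DNA replication genes fell in 19 of 20 members in LNCaP at 6 h (19 adjusted over the list alone; adjusted p = 3.64e-13), of which 8 were lower after centring. The origin licensing factor CDT1 was 2.24-fold lower (log2 -1.17 ± 0.09 SE, n = 3, adjusted p = 9.1e-07) and the ribonucleotide reductase subunit RRM2 1.86-fold lower (-0.90 ± 0.06). The vitamin D receptor VDR was 2.85-fold lower, from 372 ± 3.33 to 130 ± 6.72, and the peptide hormone gene APLN was 5.66-fold lower. The androgen receptor target FKBP5 was 1.56-fold lower (-0.64 ± 0.08, not passing after centring). Hypoxia and glycolysis genes rose in 2 and fell in 1 of 14, and 1 of 16 NF-kB and cytokine genes, NFKB2, fell (1.89-fold lower), with the same counts adjusted over the list alone. The test called 2616 of 2793 listed genes, 829 higher and 1787 lower (68.3% lower). Centring, a shift of 0.41, gave 884 higher and 386 lower, and TMM over the listed genes 884 and 484.

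In LNCaP at 24 h the same question was asked of the later response. AKR1C2 rose 109-fold and AKR1C1 49.6-fold (log2 5.63 ± 0.19), with reads that these paralogs can share. NQO1 (chromosome 16, 69743304 to 69760533, ENSG00000181019), a quinone reductase, rose 6.99-fold, from 1552 ± 46.5 to 10860 ± 540 (SD, n = 3; log2 2.81 ± 0.07 SE, adjusted p = 2e-09), and HMOX1 2.25-fold (1.17 ± 0.12). NRF2 targets rose in 24 of 28 members (24 adjusted over the list alone; adjusted p = 3.35e-22). p53 targets rose in 9 of 15 members (9 adjusted over the list alone; adjusted p = 1.21e-06), with CDKN1A 3.42-fold higher (1.77 ± 0.10) and MDM2 1.81-fold. The stress cytokine GDF15 was 4.45-fold higher (2.15 ± 0.11) and the chaperone-like CLU 4.32-fold higher (2.11 ± 0.09). Heat shock chaperones rose in 5 of 18 members (5 adjusted over the list alone), among them HSPB8 at 3.56-fold, and the list was not enriched among higher genes.

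All 20 DNA replication genes (20 adjusted over the list alone; adjusted p = 1.37e-17) and 20 of 21 mitosis genes (20 adjusted over the list alone; adjusted p = 4.86e-14) were lower in LNCaP at 24 h, and 19 and 20 stayed lower after centring. RRM2 (chromosome 2, 10262695 to 10271546, ENSG00000171848) was 3.83-fold lower, from 1837 ± 97.7 to 480 ± 28.4 (log2 -1.94 ± 0.08 SE, n = 3, adjusted p = 4.6e-08). The flap endonuclease FEN1 was 3.48-fold lower (-1.80 ± 0.12), PLK1 5.23-fold lower (-2.39 ± 0.08) and MKI67 4.64-fold lower (-2.21 ± 0.09). Unfolded protein and ATF4 genes fell in 7 and rose in 1 of 18 members (7 and 1 adjusted over the list alone; adjusted p = 0.0109 for the lower side), which became 4 and 1 after centring, with CHAC1 5.18-fold (-2.37 ± 0.18) and the serine synthesis enzyme PHGDH 1.78-fold lower. The dehydrogenase DHRS2 was 10.4-fold lower (-3.38 ± 0.16). FKBP5 was 2.03-fold lower (-1.02 ± 0.08). Hypoxia and glycolysis genes rose in 2 and fell in 2 of 14 (the 2 that fell did not pass after centring), and 1 of 16 NF-kB and cytokine genes, NFKB2, fell, with the same counts adjusted over the list alone. The test called 2335 of 2590 listed genes, 927 higher and 1408 lower (60.3% lower). Centring, a shift of 0.39, gave 1030 higher and 546 lower, and TMM over the listed genes 1022 and 956.

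PC3 at 6 h gave the early response of an androgen-independent line. HMOX1 rose 13.8-fold, from 129 ± 7.64 to 1784 ± 57.7 (SD, n = 3; log2 3.78 ± 0.08 SE, adjusted p = 4.1e-12), SLC7A11 7.36-fold (2.88 ± 0.10) and GCLM 3.64-fold (1.86 ± 0.08). NRF2 targets rose in 13 of 28 members (13 adjusted over the list alone; adjusted p = 2.07e-06). Heat shock chaperones rose in 14 of 18 (15 adjusted over the list alone; adjusted p = 2.81e-10), with BAG3 7.33-fold (2.87 ± 0.12) and DNAJB4 5.18-fold higher. The stress-induced HSP70 gene HSPA6, outside that list, was 16.2-fold higher (4.02 ± 0.17). NF-kB and cytokine genes fell in 15 of 16 members (15 adjusted over the list alone; adjusted p = 6.94e-10). IL8, the neutrophil chemokine CXCL8 (chromosome 4, 74606223 to 74609433, ENSG00000169429), went from 7041 ± 385 to 1676 ± 114, 4.20-fold lower (log2 -2.07 ± 0.07 SE, adjusted p = 8e-10). CXCL1 was 6.45-fold lower (-2.69 ± 0.09), the adhesion molecule ICAM1 5.08-fold (-2.35 ± 0.09) and IL6 4.67-fold (-2.22 ± 0.11).

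Apoptosis regulators rose in 5 and fell in 3 of 14 members in PC3 at 6 h (5 and 3 adjusted over the list alone; adjusted p = 0.036 for the higher side), but the 3 did not pass after centring and 3 rose once the GC trend was removed. PMAIP1, a death-promoting BH3 protein, was 1.67-fold higher (0.74 ± 0.09) and the death receptor TNFRSF10A 1.57-fold higher (0.65 ± 0.08). Interferon-stimulated genes fell in 5 of 8 members (5 adjusted over the list alone; adjusted p = 0.0109), of which 3 were lower after centring, with the viral RNA sensor OAS1 2.38-fold lower. DNA replication genes fell in 7 of 20 and mitosis genes in 8 of 21 members, of which 1 and 2 were lower after centring, with PLK1 1.67-fold lower (-0.74 ± 0.08). p53 targets rose in 1 and fell in 3 of 15 (2 and 2 after centring), unfolded protein and ATF4 genes rose in 4 and fell in 2 of 18 (4 and 1 after centring), and hypoxia and glycolysis genes rose in 1 and fell in 1 of 14. For these 5 lists the counts adjusted over the list alone were the same. The test called 2842 of 3004 listed genes, 1066 higher and 1776 lower (62.5% lower). Centring, a shift of 0.38, gave 1135 higher and 557 lower, and TMM over the listed genes 1135 and 893.

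At 24 h in PC3, AKR1B10 was 31.6-fold higher, from 33.7 ± 5.99 to 1067 ± 36.4 (SD, n = 3; log2 4.98 ± 0.11 SE, adjusted p = 2.1e-11). SLC7A11 was 9.21-fold higher (3.20 ± 0.13), HMOX1 3.72-fold (1.90 ± 0.10) and NQO1 3.01-fold (1.59 ± 0.06), and NRF2 targets rose in 22 of 28 members (22 adjusted over the list alone; adjusted p = 1.12e-15). Heat shock chaperones rose in 13 of 18 (15 adjusted over the list alone; adjusted p = 8.87e-08), with CHORDC1 1.89-fold and FKBP4 1.71-fold higher. Hypoxia and glycolysis genes rose in 6 of 14 members (6 adjusted over the list alone; adjusted p = 0.0155). ADM (chromosome 11, 10326642 to 10328923, ENSG00000148926) went from 125 ± 14.2 to 669 ± 21.1, 5.34-fold higher (2.42 ± 0.10, adjusted p = 1.7e-09), and the glucose transporter SLC2A1 was 2.08-fold higher (1.05 ± 0.07). Unfolded protein and ATF4 genes rose in 7 and fell in 4 of 18 (7 and 4 adjusted over the list alone; adjusted p = 0.0206 for the higher side), with the amino acid transporter subunits SLC3A2 (1.32 ± 0.06) and SLC7A5 (2.03-fold) higher while CHAC1 was 1.84-fold lower.

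Mitosis genes rose in 5 of 21 members in PC3 at 24 h (5 adjusted over the list alone), with UBE2C 1.37-fold (log2 0.45 ± 0.06 SE, n = 3) and PLK1 1.35-fold higher. DNA replication genes rose in 1 and fell in 9 of 20 (1 and 9 adjusted over the list alone; adjusted p = 0.0236 for the lower side), of which 5 were lower after centring. The kinase MAP2K6 was 12.1-fold lower, from 228 ± 14.2 to 18.3 ± 7.22 (-3.60 ± 0.18, adjusted p = 1.2e-08), and the neurotensin receptor NTSR1 was 8.29-fold lower, from 1102 ± 80.7 to 133 ± 6.3. The homeobox gene HOXB13 was 2.23-fold lower (-1.15 ± 0.07). NF-kB and cytokine genes fell in 7 of 16 members (7 adjusted over the list alone), with TNFAIP3 3.35-fold (-1.74 ± 0.12) and CXCL1 3.24-fold lower (-1.70 ± 0.09). Interferon-stimulated genes fell in 4 of 8 (5 adjusted over the list alone), with IFI44L 2.65-fold lower (-1.41 ± 0.12). p53 targets rose in 1 and fell in 4 of 15 (1 and 4 adjusted over the list alone), which became 2 and 1 after centring, and CDKN1A was not listed. The test called 3449 of 3658 listed genes, 1437 higher and 2012 lower (58.3% lower). Centring, a shift of 0.33, gave 1498 higher and 767 lower.

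**Figure D1:**
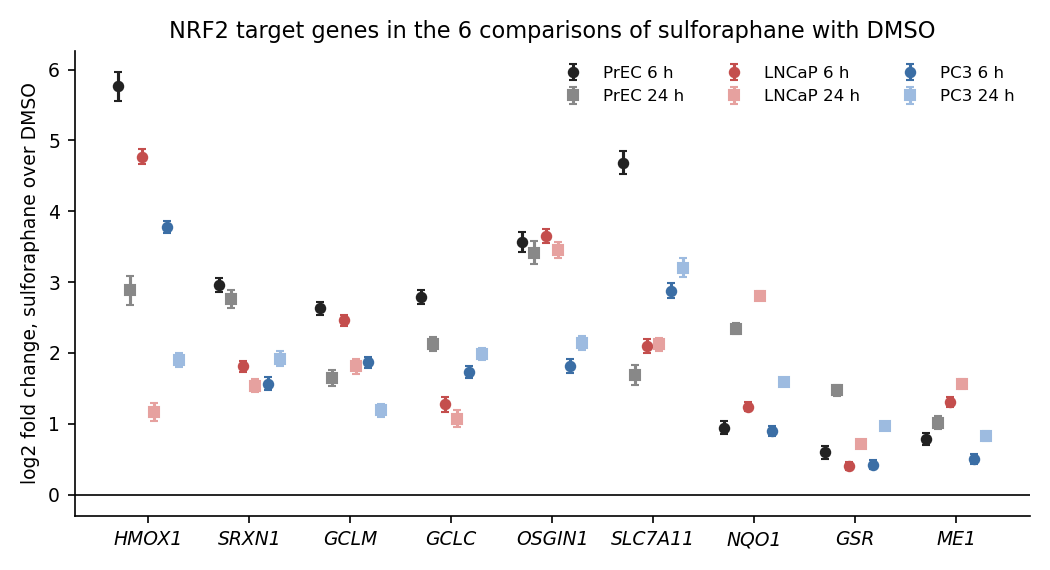
Log2 fold change of 9 NRF2 targets with sulforaphane over DMSO (error bars, SE; n = 3 libraries per group) in each cell type at 6 h and 24 h. HMOX1 is higher by 5.76 in PrEC, 4.77 in LNCaP and 3.78 in PC3 at 6 h, and NQO1 by 2.34, 2.81 and 1.59 at 24 h.

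**Figure D2:**
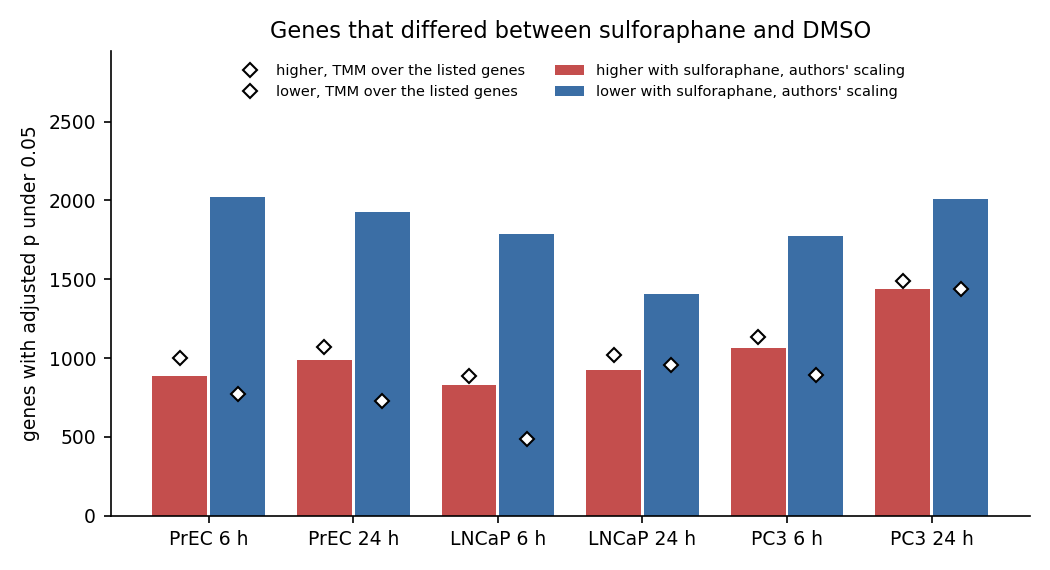
Number of genes higher and lower with sulforaphane (adjusted p under 0.05) in the 6 comparisons, as bars for the authors' scaling and white diamonds for TMM over the listed genes. More genes were lower in each comparison with the authors' scaling, from 58.3% to 69.5% of calls, and fewer were lower than higher with TMM.

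**Figure D3:**
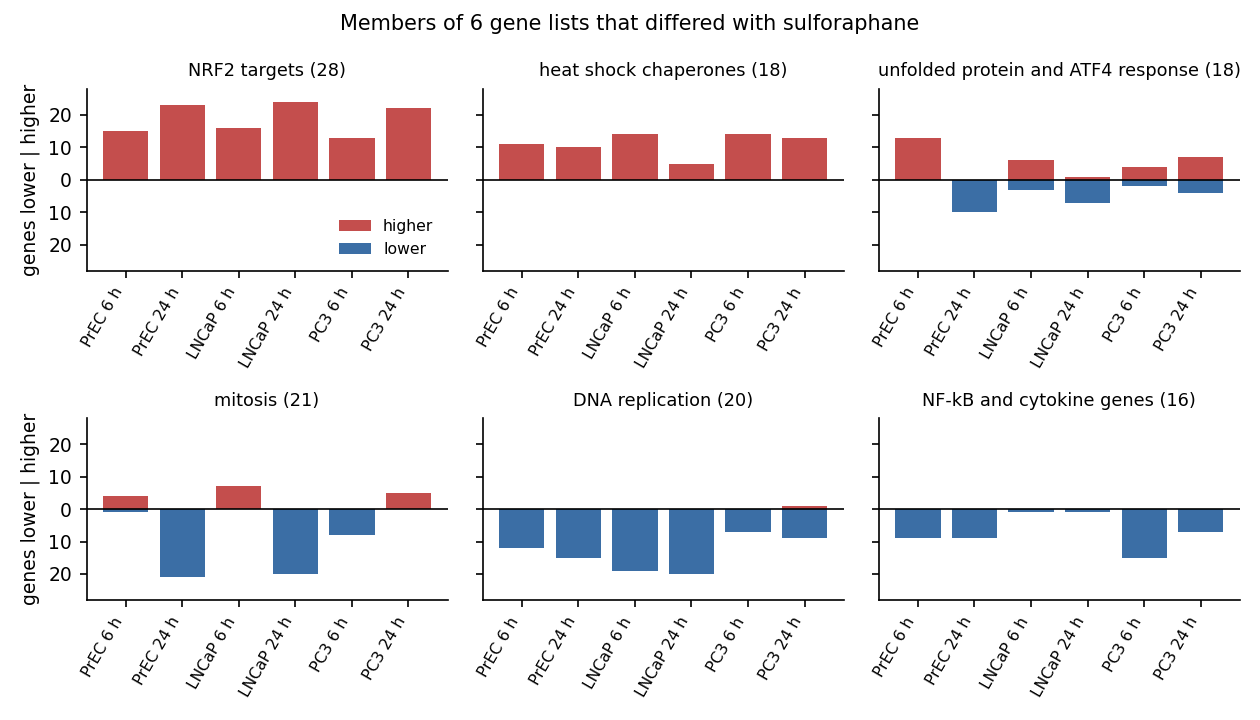
Number of members of 6 gene lists that rose (upward bars) or fell (downward bars) with sulforaphane in each comparison, with the measured members in parentheses. NRF2 targets rose in 13 to 24 of 28 members, and of the 20 replication genes, those lower in PrEC at 24 h numbered 15, or 3 after centring.

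The remaining lists moved in few members or in both directions. Of 14 apoptosis regulators, 3 rose and 3 fell in PrEC at 6 h, and 1 to 3 rose and 2 or 3 fell in both LNCaP tables and in PrEC and PC3 at 24 h, with 0 or 1 lower in each after centring. Of 14 androgen receptor targets, 0 to 4 rose and 0 to 4 fell (0 or 1 after centring), the 4 that rose being in PC3 at 24 h. Of 13 cholesterol synthesis genes, 1 or 2 rose and 0 to 2 fell (1 to 3 and 0 or 1 after centring), and of 14 immediate early genes 0 to 4 rose and 0 to 5 fell (0 to 4 and 0 to 4 after centring), with FOSL1 2.40-fold higher in PrEC at 6 h. Interferon-stimulated genes fell in 1 to 3 of 8 members in the PrEC and LNCaP tables, and after centring 0 passed edgeR's test there (at most 1 at an unadjusted p under 0.05). Of 5 metallothioneins, 2 rose in PrEC at 24 h and 2 or 3 fell elsewhere, which centring reduced to 0 by edgeR's test in PrEC at 6 h and in both LNCaP tables (at most 1 at an unadjusted p under 0.05). Histone deacetylases and DNA methyltransferases rose in 0 to 2 and fell in 2 to 6 of 14 members, and after centring 0 to 3 were lower. The maintenance methyltransferase DNMT1 was 1.61-fold lower in PrEC at 6 h (not passing after centring), 2.13-fold lower in LNCaP at 24 h (log2 -1.09 ± 0.07 SE, n = 3) and 1.56-fold lower in PC3 at 6 h. HDAC3, SP1 and TXNRD1 were not listed in any sulforaphane table.

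SP and KLF factors rose in 0 to 2 and fell in 0 to 4 of 8 members, and after centring 0 or 1 was lower. Of 10 housekeeping controls, 3 rose in PrEC at 24 h (among them ACTB by 1.83-fold and PGK1 by 1.58-fold) and 0 or 1 elsewhere, and of 22 ribosomal protein genes 0 to 2 fell, with 0 lower by edgeR's test after centring (0 at an unadjusted p under 0.05). Basal epithelial markers rose in 0 to 2 and fell in 0 to 7 of 16 members, the 7 in PC3 at 24 h, where KRT15 was 4.15-fold lower (-2.05 ± 0.14). Luminal markers rose in 0 or 1 and fell in 2 to 4 of 12, and after centring 0 to 2 were lower. The ETS factor SPDEF was 2.08-fold lower in LNCaP at 6 h and 2.62-fold lower in PC3 at 24 h. Epithelial adhesion genes rose in 0 to 3 and fell in 1 to 4 of 10 and mesenchymal genes rose in 0 or 1 and fell in 0 to 3 of 9, with 0 to 2 and 0 or 1 lower after centring. Of 4 fibroblast and smooth muscle markers, 0 or 1 rose and 0 or 1 fell in each table. The neuroendocrine marker ENO2 was higher in PC3 at 24 h (log2 0.58). It also passed as higher in PrEC at 24 h (log2 0.81), a call lost when either of 2 libraries was left out, and as lower in LNCaP at 24 h (log2 -0.72), a call lost when any of 3 libraries was left out and after centring. The endothelial marker VWF was 2.92-fold lower in LNCaP at 6 h, and of 2 leukocyte markers CD68 fell in PC3 at 24 h. Adjusted over the list alone, 4 immediate early genes fell in PrEC at 24 h and 3 luminal markers in LNCaP at 24 h, and the other counts were the same. In 264 tests of a list in a direction, 34 were enriched. Where a list had 0 calls in a direction, at most 1 listed member had an unadjusted p under 0.05 by edgeR's test. Unlisted members have no p-value, so this does not show that they were unchanged.

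Whether the response changed between 6 h and 24 h was tested gene by gene. In PrEC, 687 of 1189 genes listed at both times differed in their response (edgeR, adjusted p under 0.05), and 294 of these had changed sign. STC2, a secreted glycoprotein of the stress response, rose 8.01-fold at 6 h and was 7.77-fold lower at 24 h, a difference in log2 fold change of -5.96 ± 0.21 (SE, n = 3 libraries in each of 4 groups; adjusted p = 4.85e-09). TRIB3 differed by -4.19 and the mitotic kinesin KIF14 by -4.08. In LNCaP, 380 of 1047 genes differed and 87 changed sign. The HMOX1 response was smaller at 24 h (difference -3.60, adjusted p = 7.8e-11), and those of the mitotic genes UBE2C (-2.37) and AURKA (-2.22) were lower. In PC3, 476 of 1319 genes differed and 138 changed sign, and the cytokine IL11 differed by 3.01. Across genes, which are not independent replicates, the log2 fold changes at both times correlated with r = 0.32 in PrEC, 0.73 in LNCaP and 0.69 in PC3. Genes listed at 1 time alone (in PrEC 2062 at 6 h and 2116 at 24 h) entered neither the tests nor these correlations. Each difference also holds the change of the DMSO cells between the times.

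Whether the cell types responded differently was tested in the same way. Only genes listed in both comparisons could be tested, so genes that passed the authors' thresholds in 1 cell type alone are missing. In every pair these outnumbered the tested genes, with 1925 listed in PrEC alone and 1467 in LNCaP alone at 6 h. At 6 h, 503 of 1326 genes differed between PrEC and LNCaP, 507 of 1382 between PrEC and PC3 and 256 of 1187 between LNCaP and PC3. The signs were opposite for 45, 61 and 51 of these. CHAC1, which rose in PrEC and fell in LNCaP, differed by -5.62 (LNCaP minus PrEC), STC2 differed by -3.72 between PrEC and LNCaP and by -3.30 between PrEC and PC3, and the carbonyl reductase CBR3 by -3.34 between LNCaP and PC3. At an adjusted p of 0.01 the counts for PrEC against LNCaP and LNCaP against PC3 dropped to 304 and 160. At 24 h, 370 of 1079 genes differed between PrEC and LNCaP, 568 of 1255 between PrEC and PC3 and 378 of 919 between LNCaP and PC3, with 76, 203 and 166 of opposite sign. PLK1 fell in LNCaP and rose in PC3, a difference of 2.82 (adjusted p = 3.65e-11), and RRM2 differed by 2.38 and UBE2C by 2.36. Between PrEC and LNCaP, FTL differed by -2.62 and the membrane protein TM4SF1 by -3.16.

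The sharing of responses was tested with Fisher's exact test on genes called the same way with the authors' scaling. The background joined genes listed in the cell type comparisons of both sides with genes listed in both sulforaphane comparisons. At 6 h, 330 genes were higher and 833 lower in both PrEC and LNCaP, where independent lists would share 54.2 and 297.9. PrEC and PC3 shared 394 higher and 790 lower genes (71 and 293.9 if independent), and LNCaP and PC3 shared 380 and 675 (66.8 and 260.1). At 24 h the shared counts were 241 and 637 (67.4 and 219.7), 352 and 537 (106.1 and 303.6) and 288 and 350 (96.4 and 224.3) for the same pairs. Between times, PrEC shared 173 higher and 489 lower genes (65.3 and 291.3), LNCaP 272 and 564 (57.3 and 199.3) and PC3 400 and 654 (115.3 and 279.1). The largest adjusted p of these 18 tests was 1.22e-20. The background held every gene listed in both sulforaphane comparisons but left out some called in only 1. Of 887 higher and 2022 lower genes in PrEC at 6 h, 795 and 1870 entered the test with LNCaP. This leans the counts for independent lists and the p-values toward sharing, by an amount that was not measured. Higher in all 6 comparisons were 35 genes, among them HMOX1, SLC7A11, SRXN1, GCLM, GCLC, NQO1, GSR, ME1 and OSGIN1. Lower in all 6 were 33 genes, among them UHRF1, LIG1, MCM4 and POLD1, as counted with the authors' scaling.

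DMSO cells were compared to ask how the cancer lines differ from normal epithelium without treatment. In LNCaP, the basal keratin KRT5 (chromosome 12, 52908359 to 52914243, ENSG00000186081) was 1507-fold lower than in PrEC at 6 h, 119 ± 22.9 against 179900 ± 15580 (SD, n = 3; log2 -10.56 ± 0.21 SE, adjusted p = 4e-13), and 1502-fold lower at 24 h. Basal epithelial markers were lower in 15 of 16 members at both times (15 adjusted over the list alone; adjusted p = 6.72e-09 and 1.14e-06), including the basal transcription factor TP63, 1795-fold lower at 24 h (-10.81 ± 0.14). Luminal markers were higher in 9 and lower in 2 of 12 members at 6 h and in 8 and 2 at 24 h, and androgen receptor targets were higher in 10 and lower in 2 of 14 and in 9 and 3. KLK3 was 2671-fold higher at 24 h (11.38 ± 0.16). NF-kB and cytokine genes were lower in LNCaP in 11 of 16 members at 6 h and in all 16 at 24 h (adjusted p = 0.000279 and 4.08e-08), with IL1B 958-fold lower and CXCL2, at 0 counts in LNCaP, at least 78.6-fold lower at 6 h. Immediate early genes were higher in 1 and lower in 12 of 14 at 6 h and higher in 1 and lower in 13 at 24 h (adjusted p = 1.16e-05 and 1.05e-05 for the lower side), with FOSL1 109-fold lower at 6 h and the ERK phosphatase DUSP6 252-fold lower. The mesenchymal filament VIM was 94.1-fold lower at 6 h (-6.56 ± 0.14).

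Between PrEC and LNCaP, DNA replication genes were higher in LNCaP in 11 and lower in 1 of 20 members at 6 h and higher in 19 at 24 h (adjusted p = 0.000614 at 24 h). After centring the 6 h counts turned to 2 higher and 5 lower, and 13 were higher at 24 h. Cholesterol synthesis genes were lower in 7 of 13 at 6 h (adjusted p = 0.0243) and higher in 1 and lower in 6 at 24 h, with the squalene epoxidase SQLE 4.28-fold lower at 6 h. Unfolded protein and ATF4 genes were higher in 9 and lower in 7 of 18 at 6 h, which centring turned to 5 and 7, and higher in 2 and lower in 12 at 24 h (adjusted p = 0.00365 for the lower side), with CHAC1 11.1-fold higher at 6 h and 5.91-fold lower at 24 h. From 6 h to 24 h in DMSO, CHAC1 changed by 5.29 in PrEC and -0.68 in LNCaP (log2), so its reversal came mostly with PrEC. Over the measured members of the list the median changes were 1.25 and -0.11. Ribosomal protein genes were higher in 13 and lower in 1 of 22 at 6 h and higher in 16 at 24 h, but after centring 5 were lower at 6 h and 0 higher by edgeR's test (0 at an unadjusted p under 0.05), and at 24 h 4 were higher and 3 lower. The counts adjusted over the list alone were the same in each of these lists. The test called 7860 of 8108 listed genes at 6 h, 5544 higher and 2316 lower in LNCaP, and 9149 of 9293 at 24 h, 6047 and 3102. Centring, shifts of 0.75 and 0.59, gave 2952 higher and 2768 lower at 6 h and 3707 and 3607 at 24 h. TMM over all genes with counts in both groups gave 3767 and 2370 at 6 h and 4581 and 3133 at 24 h.

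Relative to PrEC, PC3 also had little basal keratin. KRT14 (chromosome 17, 39738531 to 39743147, ENSG00000186847) was 1478-fold lower at 6 h, 23.8 ± 2.48 against 35220 ± 3302 (SD, n = 3; log2 -10.53 ± 0.15 SE, adjusted p = 2e-11), and 1216-fold lower at 24 h. Basal markers were lower in 14 of 16 members at 6 h (15 adjusted over the list alone; adjusted p = 6.56e-07) and in 15 at 24 h (15 adjusted over the list alone; adjusted p = 1.27e-06). N-cadherin, CDH2, was 246-fold higher at 6 h (7.94 ± 0.17) and E-cadherin, CDH1, 7.88-fold lower (-2.98 ± 0.07). Epithelial adhesion genes were higher in 2 and lower in 5 of 10 at 6 h and higher in 3 and lower in 6 at 24 h, and mesenchymal genes were higher in 5 and lower in 3 of 9 and in 4 and 3. Cholesterol synthesis genes were lower in 11 and 12 of 13 members (adjusted p = 2.01e-05 and 3.01e-05), with squalene synthase FDFT1 27.8-fold lower at 6 h (-4.79 ± 0.09). At 24 h all 18 unfolded protein and ATF4 genes were lower in PC3 (18 adjusted over the list alone; adjusted p = 6.72e-09), with DDIT4 114-fold (-6.83 ± 0.11) and SESN2 17.4-fold lower, whereas at 6 h 6 were higher and 6 lower. From 6 h to 24 h in DMSO, the measured unfolded protein and ATF4 genes changed by a median of 1.25 in PrEC and -0.86 in PC3 (log2). p53 targets were higher in 1 and lower in 9 of 15 at 6 h and higher in 2 and lower in 11 at 24 h (adjusted p = 0.012 and 0.00228 for the lower side), and CDKN1A was 34.2-fold lower at 24 h (-5.09 ± 0.20).

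NF-kB and cytokine genes were higher in PC3 than in PrEC in 11 and lower in 4 of 16 members at 6 h, with IL8 26.6-fold higher (log2 4.74 ± 0.10 SE, n = 3), but higher in 3 and lower in 11 at 24 h (adjusted p = 0.00431 for the lower side), with PTGS2 89.7-fold lower. Over the measured members of this list, DMSO cells changed from 6 h to 24 h by a median of 0.72 in PrEC and -1.62 in PC3 (log2). Mitosis genes were higher in 6 and lower in 7 of 21 at 6 h (2 and 7 after centring) and higher in 14 at 24 h (adjusted p = 0.00467), and replication genes were higher in 9 and lower in 2 of 20 at 6 h and higher in 17 at 24 h (adjusted p = 0.00365), with the thymidylate synthase gene TYMS higher at 24 h (2.17 ± 0.09). Interferon-stimulated genes were higher in 6 and 7 of 8 (3 and 5 after centring), with ISG15 12.9-fold higher at 6 h (3.69 ± 0.11). Immediate early genes were lower in 7 and higher in 5 of 14 at 6 h and lower in 11 and higher in 3 at 24 h (adjusted p = 0.000953 for the lower side), with EGR1 134-fold lower at 6 h. Ribosomal protein genes were lower in 16 and higher in 4 of 22 at both times (adjusted p = 2.01e-05 and 0.000173 for the lower side), with RPL18 2.58-fold lower at 6 h. Luminal markers were higher in 4 and lower in 2 of 12 at 6 h, which centring turned to 1 and 2, and higher in 5 and lower in 2 at 24 h, with HOXB13 29.0-fold higher (4.86 ± 0.11). The counts adjusted over the list alone were the same in each of these lists. The test called 6897 of 7151 listed genes at 6 h, 4371 higher and 2526 lower in PC3, and 8478 of 8594 at 24 h, 5313 and 3165. Centring, shifts of 0.63 and 0.51, gave 2431 higher and 2702 lower at 6 h and 3451 and 3337 at 24 h. TMM over all genes with counts in both groups gave 3546 and 2595 at 6 h and 4236 and 3219 at 24 h.

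LNCaP and PC3 were compared as an androgen-dependent and an androgen-independent line. KLK3 (chromosome 19, 51358171 to 51364020, ENSG00000142515) was 2344-fold lower in PC3 at 6 h, 3.91 ± 0.78 against 9520 ± 267 (SD, n = 3; log2 -11.20 ± 0.12 SE, adjusted p = 3e-20), and 1503-fold lower at 24 h (-10.55 ± 0.13). Luminal markers were lower in PC3 in 11 of 12 members at 6 h (adjusted p = 0.012) and 8 at 24 h, and androgen receptor targets were lower in 11 and higher in 2 of 14 at 6 h and lower in 10 and higher in 1 at 24 h (adjusted p = 0.0405 at both times for the lower side). VIM was 178-fold higher at 6 h (7.48 ± 0.10), CDH2 622-fold higher (9.28 ± 0.15) and CDH1 8.25-fold lower (-3.04 ± 0.07). Epithelial adhesion genes were lower in all 10 members at 6 h (adjusted p = 0.00385) and in 7 at 24 h, mesenchymal genes were higher in 4 of 9 at 6 h and higher in 5 and lower in 1 at 24 h, and basal markers were higher in 7 and 9 of 16, with the laminin subunit LAMB3 198-fold higher at 6 h. NF-kB and cytokine genes were higher in 14 of 16 at 6 h (adjusted p = 7.41e-05) and higher in 11 and lower in 2 at 24 h (adjusted p = 0.033 for the higher side), with IL8 1669-fold higher at 6 h (10.71 ± 0.14). Immediate early genes were higher in 11 and lower in 1 of 14 at 6 h (adjusted p = 0.00661 for the higher side) and higher in 8 and lower in 2 at 24 h, with FOSL1 560-fold higher at 6 h, and interferon-stimulated genes were higher in 6 and 7 of 8 (adjusted p = 0.039 and 0.0192).

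Mitosis genes were higher in PC3 than in LNCaP in 9 and lower in 6 of 21 at 6 h and higher in 11 and lower in 1 at 24 h (adjusted p = 0.033 for the higher side). Replication genes were higher in 5 and lower in 7 of 20 at both times, a balance that centring turned to 6 and 2 at 6 h and 5 and 3 at 24 h, with MCM2 2.09-fold lower at 6 h. Ribosomal protein genes were lower in 17 and higher in 2 of 22 at 6 h and lower in 17 and higher in 1 at 24 h (18 lower adjusted over the list alone; adjusted p = 0.0228 and 0.00473 for the lower side), with RPL7A 4.49-fold lower at 6 h (log2 -2.17 ± 0.07 SE, n = 3). Cholesterol synthesis genes were lower in 9 and higher in 1 of 13 at 6 h and lower in 10 and higher in 1 at 24 h (adjusted p = 0.0405 at 24 h for the lower side), p53 targets lower in 11 and higher in 2 of 15 and lower in 9 and higher in 2, and unfolded protein and ATF4 genes lower in 10 and higher in 7 of 18 and lower in 12 and higher in 2. In the other lists the counts adjusted over the list alone were the same. The test called 9029 of 9163 listed genes at 6 h, 3868 higher and 5161 lower in PC3, and 8859 of 9090 at 24 h, 4112 and 4747. Shifts of 0.42 and 0.37 on the log2 scale, by centring, gave 3965 higher and 3755 lower at 6 h and 4196 and 3520 at 24 h. TMM over all genes with counts in both groups gave 3904 and 4692 at 6 h and 4164 and 4598 at 24 h.

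**Figure D4:**
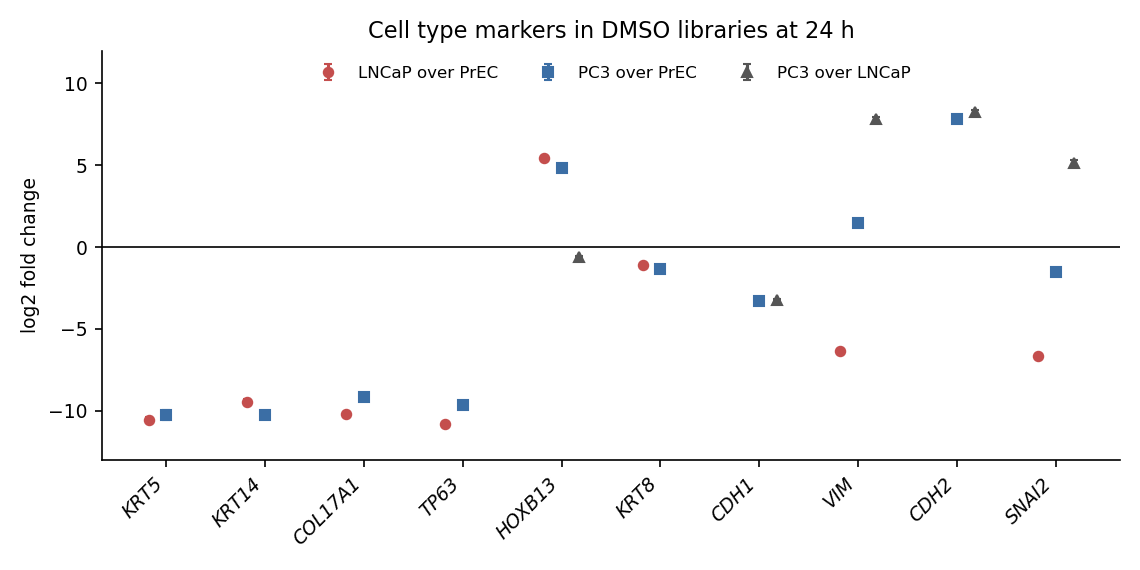
Log2 fold change of 10 lineage genes between DMSO cells at 24 h for 3 pairs of cell types (error bars, SE; n = 3 libraries per group), with no point where a gene was not listed or not called. KRT5 stands at -10.55 in LNCaP and -10.28 in PC3 relative to PrEC, and CDH2 at 8.24 in PC3 relative to LNCaP.

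The other lists gave smaller or mixed differences between DMSO cells. NRF2 targets were higher in 12 and lower in 7 of 28 members in LNCaP relative to PrEC at 6 h, where centring gave 9 and 10, and in 11 and 10 at 24 h, where it gave 7 and 11. In PC3 they were higher in 8 and lower in 9 relative to PrEC at 6 h and in 10 and 10 at 24 h (5 and 10 after centring), and relative to LNCaP higher in 6 and lower in 15 at 6 h (6 and 9 after centring) and in 8 and 11 at 24 h (8 and 8 after centring). Heat shock chaperones were higher in 6 and lower in 3 of 18 in LNCaP relative to PrEC at 6 h, which centring turned to 1 and 5, and higher in 10 and lower in 4 at 24 h. In PC3 they were higher in 5 and lower in 2 relative to PrEC at 6 h (lower in 3 after centring) and higher in 10 and lower in 3 at 24 h, and relative to LNCaP higher in 4 and lower in 5 at 6 h (4 and 3 after centring) and in 4 and 6 at 24 h (5 and 5 after centring). Histone deacetylases and DNA methyltransferases were higher in 10 and lower in 0 to 2 of 14 members in LNCaP and in PC3 relative to PrEC at both times, and 4 to 6 were higher after centring. HDAC9 was 36.2-fold lower in LNCaP than in PrEC at 6 h and 2.41-fold higher in PC3. Mitosis genes were higher in 4 and lower in 4 of 21 in LNCaP relative to PrEC at 6 h and in 10 and 3 at 24 h, which centring turned to 2 and 6 and to 4 and 4. p53 targets were higher in 7 and lower in 7 of 15 in LNCaP relative to PrEC at 6 h and in 5 and 8 at 24 h, and adhesion genes were higher in 7 of 10 at 6 h (3 higher and 1 lower after centring) and higher in 8 and lower in 1 at 24 h (3 and 3 after centring).

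For the remaining lists the counts are given as ranges over the 6 tables. Apoptosis regulators were higher in 3 to 6 and lower in 4 to 6 of 14 members, hypoxia and glycolysis genes higher in 2 to 7 and lower in 2 to 6 of 14, and SP and KLF factors higher in 2 to 4 and lower in 2 or 3 of 8. Androgen receptor targets in PC3 relative to PrEC were higher in 3 and lower in 3 of 14 at 6 h and in 3 and 5 at 24 h. Housekeeping controls were higher in 2 to 5 and lower in 2 to 4 of 10, with ACTB 3.00-fold lower in LNCaP than in PrEC at 6 h. Metallothioneins were higher in 1 or 2 and lower in 2 or 3 of 5, with MT2A 14.2-fold lower in LNCaP than in PrEC at 6 h. Interferon-stimulated genes were higher in 2 and lower in 2 or 3 of 8 in LNCaP relative to PrEC, where mesenchymal genes were higher in 2 and lower in 4 of 9 at both times. Fibroblast and smooth muscle markers were higher in 0 to 2 and lower in 1 or 2 of 4. ENO2 was higher in the cancer lines in all 4 tables with PrEC, 13.0-fold in PC3 and 2.71-fold in LNCaP at 6 h, and higher in PC3 than in LNCaP. VWF was higher in LNCaP than in PrEC and in PC3, and both leukocyte markers were lower in both lines than in PrEC, with CD74 67.8-fold lower in LNCaP at 6 h. Over all lists in the cell type tables, 35 of 264 tests were enriched and 29 depleted, or 31 and 1 with an absolute log2 fold change of at least 1.

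Genes that set the cancer lines apart from PrEC overlapped. At 6 h, 3506 genes listed in both tables with PrEC were called the same way in LNCaP and PC3, 2314 higher and 1192 lower, and 1118 were called in opposite ways, whereas independent lists would share 1788.6 and 638.6. At 24 h, 4747 were called the same way, 3044 higher and 1703 lower, with 1444 opposite and 2292.1 and 944.7 if independent. These counts rest on the authors' scaling and were not made again after centring. Centring changed the sign of 1357 called genes between PrEC and LNCaP and of 720 between PrEC and PC3 at 6 h. At 24 h it changed the sign of 1289 and 823. Both tables of a time use the same PrEC libraries. In 1000 simulations without any effect that kept these shared libraries, 0 genes on average passed a z test the same way in both tables. The spread was taken from edgeR's dispersions, and at an unadjusted p under 0.05 the mean was 45.6 at 6 h and 58.3 at 24 h. The simulated log2 fold changes correlated with a mean r of 0.5 across genes, against 0.65 and 0.64 in the data. Without effect, a shared group gives an r of 0.5 by construction, so this value cannot be used to judge the excess. How much of the excess came from the shared libraries or from the scaling was not measured. Between 6 h and 24 h, 6942 genes kept their direction between PrEC and LNCaP and 58 changed it, 5808 and 121 between PrEC and PC3, and 7636 and 37 between LNCaP and PC3.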

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

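The splits of libraries for the differences and the tests of the GC content, of linear trends with gene length or GC content, of the authors' scaling and of control cells that moved between the times were chosen only after results had been seen. Each result in the next 3 paragraphs was singled out because the effect of sulforaphane differed between 2 times or 2 cell types by a test of the difference itself (edgeR contrast, adjusted p under 0.05), and the values are from the 10 largest differences of log2 fold change, the second minus the first.

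Between 6 h and 24 h, 687 genes differed in PrEC, led by CHAC1 (-7.84), ADM2 (-6.98), STC2 (-5.96), KIF18A (-4.53), TRIB3 (-4.19), SLC1A4 (-4.15), JDP2 (-4.14), KIF14 (-4.08), SLC6A9 (-3.97) and CENPE (-3.88). CHAC1 at 24 h was -3.94, and -5.41 without 1 of the sulforaphane libraries. In LNCaP 380 differed, led by HMOX1 (-3.60), AKR1C2 (3.20), HSPA1B (-3.00), FAM83D (-2.56), PIF1 (-2.52), KIF20A (-2.51), UBE2C (-2.37), ANLN (-2.34), BUB1 (-2.32) and AURKA (-2.22). In PC3 476 differed, led by HSPA1A (-3.78), HSPA1B (-3.41), IL11 (3.01), PFKFB4 (2.59), ELF3 (2.38), APLN (2.28), WNT9A (2.09), APOL2 (2.02) and HOXA11 (2.02). HSPA1A and HSPA1B can share reads, as can AKR1C1 and AKR1C2.

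At 6 h, 503 genes differed between PrEC and LNCaP, led by CHAC1 (-5.62), STC2 (-3.72), EPN3 (2.82), SLC7A11 (-2.59), ID3 (2.51), JDP2 (-2.45), ALOXE3 (-2.31), GADD45B (-2.27), CCDC85B (-2.20) and FERMT2 (-2.11). Between PrEC and PC3 507 differed, led by STC2 (-3.30), CXCR7 (-3.22), CXCL2 (2.82), ID3 (2.54), RPP25 (2.42), NOTCH1 (2.14), C12orf66 (2.13), FGD6 (-2.03), IL7R (-1.99) and HMOX1 (-1.98). Between LNCaP and PC3 256 differed, led by CBR3 (-3.34), CXCR7 (-2.50), ELF3 (-2.37), PTGR1 (-1.93), OSGIN1 (-1.83), HSPA6 (1.71), CDKN1A (-1.68), LPXN (-1.58), FZD5 (1.5) and CCDC85B (1.49).

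At 24 h, 370 genes differed between PrEC and LNCaP, led by TM4SF1 (-3.16), TMEM40 (2.72), ULBP1 (2.67), CYP4F11 (-2.66), FTL (-2.62), AQP3 (2.60), HIST1H1C (-2.58), PPIF (-2.49), KCNAB2 (-2.42) and TSC22D3 (2.25). Between PrEC and PC3 568 differed, led by STC2 (4.68), CXCR7 (-3.46), ITGB2 (-3.08), CHAC1 (3.05), KIF18A (2.96), HJURP (2.81), AKR1C1 (-2.77), GLRX (-2.71), NDC80 (2.55) and SPTSSB (2.49). Between LNCaP and PC3 378 differed, led by VSIG10L (-3.22), PLK1 (2.82), STC2 (2.69), PSRC1 (2.58), FAM43A (-2.50), FAM64A (2.43), RRM2 (2.38), UBE2C (2.36), NEIL3 (2.35) and CDCA2 (2.33).

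More genes were lower than higher with sulforaphane in all 6 tables. Each library's linear trend was removed, with the background genes as reference. This left at least 58.3% of calls lower for gene length, and 63% at 6 h and 58.6% at 24 h for GC content. These values argue against a linear bias with that reference as the whole cause. The removal could move folds little, since listed and background genes had similar mean GC (50.44% and 49.38% in PrEC at 6 h). At 6 h the GC slopes of sulforaphane and DMSO libraries differed by 2.07 (PrEC), 1.08 (LNCaP) and 1.17 (PC3) times the largest range within a group. At 24 h these were 0.45, 0.14 and 0.4. In PrEC at 6 h the log2 fold changes correlated with GC content at r = -0.49. The source of this trend was not tested. Bias of another shape stays open, since the lowest length class had 50.4% lower (PC3 at 6 h, after 73.5% and 64% in shorter classes), within its counting spread of 50%, and the lowest GC class had 36.9% at 6 h and 50.8% at 24 h. Rising genes that take a larger share of the counts would lower all others, and this made up at most 0.66 of the shift needed to even the split, so it stays open, as does the authors' scaling, since TMM over the listed genes, selected for a difference, left at most 49.2% lower (of calls of at least 2-fold, 62% in LNCaP and 63.8% in PC3 at 24 h and 13.1% to 41.8% in the other 4). A real fall in more genes than rose was not separated from these.

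ATF4 and unfolded protein genes were higher at 6 h and lower at 24 h in PrEC. The authors' scaling would not produce the fall at 24 h, since at least 9 members stayed lower after centring. Centring raised every log2 fold change, so it could not test the rise at 6 h. Nor would 1 deviating library produce the rise or the fall, since at least 10 members stayed called at each time without any 1 library. The drop of the effect is, by arithmetic, the rise in DMSO cells minus the change in cells with sulforaphane. DMSO cells that moved between the times therefore supply a part of it, and the size of that part over the list stays open. The median rise in DMSO over all 18 members was 0.52 of the drop of the median effect over listed members. The 95% interval of this ratio, drawn over members, which are not independent replicates, was 0.31 to 0.72, too wide to settle that size. Over the 9 members with values in DMSO and in both sulforaphane comparisons, the ratio was 0.73. Their median change was 2.35 in DMSO cells and -1.10 in cells with sulforaphane.

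Replication and mitosis genes were lower at 24 h in LNCaP and PrEC. The authors' scaling would not produce this for mitosis in both and replication in LNCaP, where at least 95% of called members stayed lower after centring, but it remains possible for replication in PrEC, where 20% did. Control cells that raised these genes between the times were tested as well, and the median rise in DMSO over all measured members was at most 0.12 of the median effect over listed members (upper limit of the 95% interval 0.14). A slower cell cycle with sulforaphane is consistent with the 95% and was not measured directly.

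Splits of the libraries were used as a check on the grouping. For each of the 12 tables, the real split (1 of 10) gave as many calls as reported and the highest other split gave 0, or 1 for LNCaP and PC3 with sulforaphane at 6 h. For each of the 9 differences the real split was 1 of 82 and the highest other gave 0. With 10 splits no share under 0.05 is possible, and the genes were listed for the real split, so these values do not test it.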

How the results depend on the processing

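Counts of calls kept within 1.5 times of the value in the report, wherever the setting was run, with an adjusted p under 0.01 (33 of 35 counts), an FPKM of at least 1, adjustment over listed genes only, 1 entry per symbol, DESeq2, the authors' count and Cuffdiff tests, their p-values adjusted again, standard errors from those p-values, another background and, for cell types, TMM over all genes with counts in both groups. The listed genes had already passed the authors' tests, so their count test passes every gene listed with counts by construction. This selection also made it likely that other tests on the same genes would agree. The cause was not tested for the following, except that a minimum fold leaves fewer genes by construction. With an absolute log2 fold change of at least 1, sulforaphane calls were 876, 844 (PrEC, 6 h and 24 h), 286, 521 (LNCaP), 405 and 429 (PC3). Cell type calls were 4987, 5174 (PrEC and LNCaP), 3755, 4229 (PrEC and PC3), 4917 and 4954 (LNCaP and PC3). Overlaps between times were 105 (PrEC), 79 (LNCaP) and 83 (PC3). Overlaps between cell types, in the order PrEC and LNCaP, PrEC and PC3, LNCaP and PC3, were 88, 122 and 56 at 6 h and 230, 72 and 44 at 24 h. Overlaps of cell type calls were 1772 and 1966 for LNCaP and PC3 against PrEC at 6 h and 24 h, and 4070, 2866 and 4081 between times. Centring left 1594 and 1542 calls in PrEC, 1270 in LNCaP at 6 h and 1692 and 2265 in PC3. TMM over the listed genes left 1776 and 1796 in PrEC and 1368 in LNCaP at 6 h, and removing the GC trend left 1928 in PrEC at 6 h. By the percentile of the median among matched random lists, 58 lists in cell type comparisons stood in the outer 2.5%, and at an adjusted p under 0.01 the differences were 304 (PrEC and LNCaP, 6 h) and 160 (LNCaP and PC3, 6 h).

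Without 1 library at a time, sulforaphane calls ranged from 2553 to 3119 and 2329 to 3111 (PrEC), 2282 to 2545 and 1912 to 2300 (LNCaP) and 2510 to 2859 and 3046 to 3421 (PC3). Cell type calls ranged from 7622 to 7958 and 8994 to 9119 (PrEC and LNCaP), 6624 to 7000 and 8306 to 8418 (PrEC and PC3) and 8867 to 8970 and 8586 to 8794 (LNCaP and PC3). Enriched lists ranged from 33 to 36 and, for cell types, from 34 to 37. Differences ranged from 634 to 707, 334 to 403 and 434 to 492 between times, from 396 to 681, 443 to 688 and 212 to 270 between cell types at 6 h and from 319 to 389, 504 to 616 and 343 to 381 at 24 h. Overlaps ranged from 555 to 698, 695 to 823 and 959 to 1066 between times, from 1070 to 1201, 1082 to 1224 and 951 to 1059 at 6 h and from 762 to 896, 737 to 921 and 539 to 641 at 24 h. Overlaps of cell type calls ranged from 3338 to 3626, 4617 to 4742, 6811 to 6953, 5633 to 5843 and 7463 to 7618. By the ratio of FPKM, 72 of 171 folds of named genes with a pseudocount of 1 and 26 with a pseudocount of 0.1 moved by more than the spread between libraries. Of the folds, HSPA1A in LNCaP relative to PrEC at 24 h turned to a log2 fold change of 0.39 by FPKM, whose cause was not tested. KLK3 in PrEC at 24 h passed with DESeq2 and fell from a log2 fold change of 2.67 to 0.74 without 1 library, and centring ended the calls of CDT1 and DNMT1 in PrEC at 6 h, of FKBP5 in LNCaP at 6 h and ENO2 in LNCaP at 24 h. No paired analysis was possible because the columns name the group but not the replicate number, so the planned replicate block was not run. Library numbers fall in 2 sets, of 2 and 1 libraries per group, whose meaning the labels do not give. With the set as a replicate block, an alternative added later, sulforaphane calls were 2974 and 2849 (PrEC), 2518 and 2466 (LNCaP) and 2915 and 3583 (PC3), and cell type calls 7828 and 9142 (PrEC and LNCaP), 6820 and 8498 (PrEC and PC3) and 9030 and 8959 (LNCaP and PC3). Unlisted genes limit every count, and changes of 1.5-fold were recovered least often in simulated data (38.8% to 83.6% for sulforaphane).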

Other observations

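DMSO cells themselves changed between 6 h and 24 h, which no deposited table compares (edgeR, TMM over the genes listed with counts at both times, adjusted p under 0.05). In PrEC 2087 of 10234 genes were higher and 1985 lower at 24 h, with 16 of 18 measured unfolded protein and ATF4 genes and 10 of 15 NF-kB and cytokine genes higher and 15 of 17 replication genes lower. In PC3 1858 of 10609 genes were higher and 2006 lower, with 15 of 18 unfolded protein and ATF4 genes and 14 of 16 NF-kB and cytokine genes lower and 13 of 15 mitosis genes higher. In LNCaP 10 of 10599 genes were higher and 11 lower. The times may also have been sequenced apart, since no label gives the run, so these changes hold time and any such difference together.

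In PrEC, the 9 unfolded protein and ATF4 genes listed at both times, whether called or not, had a median sulforaphane effect of 1.32 at 6 h. At 24 h it was -1.91 on the log2 scale, with ATF3 alone on the higher side (0.51). Their median change from 6 h to 24 h was 2.35 in DMSO cells and -1.10 in cells with sulforaphane.

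HSPA1A was lower in LNCaP than in PrEC at 24 h by counts (log2 -4.73) and higher by the deposited FPKM (0.39).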
